A study of Mus musculus with 6 samples.

How the data were processed

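Bulk RNA was measured in 6 libraries of CD8+ T cells from mouse liver, 3 in the control group and 3 in the CUMS group, as the sample titles assign them. RNA was extracted with TRIzol, and mRNA was fragmented and reverse transcribed with random primers into libraries, per the labels' protocols. The submitters' processing notes name fastp for read trimming and filtering, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the genome build mm10. The deposited values are raw read counts per gene, whole numbers with no normalization, for 54532 genes. The gene annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Coordinates and gene names are those of the deposited table, in mm10. Some genes of the fixed lists were not analysed here.

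Total counts per library were 14902248 to 18023206. A gene with 0 counts in a library may have up to 3 counts by chance, which is 0.166 to 0.201 CPM. Intervals of shares are exact Clopper-Pearson intervals at the 95% level, and since reads without molecular identifiers are not independent molecules, intervals and floors cover counting error only. No pair of libraries within a group agreed within counting noise: the chi-square per gene between such pairs was 10.7 to 38.5.

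The counts were tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr at its defaults (14054), TMM library factors, dispersion estimated over all 6 libraries, a quasi-likelihood F test (glmQLFit in its legacy form, glmQLFTest) of CUMS against control with no other covariate, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. The biological coefficient of variation was 29.8%. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are scaled by the TMM factors, and group values are mean ± SD of 3 libraries. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so none is reported for single values.

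Gene lists, 30 of biological processes and 10 of markers of other cell types, were fixed before the data were examined, as were the tests, the alternatives and the rule for the genes named. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all 40 lists, and with an estimated correlation and fry as alternatives. Genes named are the 10 protein-coding genes with the largest fold change in each direction among those past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, up to 4 members per list with the smallest p, and 16 genes fixed by name; some genes that this rule takes are not reported here. Rbm3, in the closing observations, lies outside that rule and was chosen after its values were seen.

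The alternatives were median-of-ratios size factors, library size alone, no filter and a stricter filter (at least 1 CPM in 3 libraries and a mean of 50 counts), DESeq2 1.42.0, limma voom with sample quality weights, a log2 fold change over 1, the replicate number as a block, each library left out in turn, protein-coding genes only, marker genes of other cell types left out, the hepatocyte marker level as a covariate, and list genes on 1 list only. Added after the data were seen were fits without CUMS replicates 2 and 3, with genes of at least 10 CPM only, with the monocyte and neutrophil marker level as a covariate, and with each library's trend with transcript GC content removed (GENCODE annotation of the same build; 14043 genes had a GC value).

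The steps were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed. Among 13427 genes tested, edgeR made 108 calls, of which 10 were false, a larger share than the adjusted threshold aims for. It made 1 call when nothing was changed. Of 50 genes changed by each size, edgeR recovered 20% at 1.5-fold, 42% at 2-fold, 76% at 3-fold and 58% at 4-fold. A gene that missed the threshold is therefore not shown to be unchanged. The simulation gave every library the same spread per gene. It did not copy the many unread low-abundance genes that the Results give for CUMS replicates 2 and 3. These rates may therefore not hold for the real libraries. Figures were drawn with matplotlib 3.10.9.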

Results

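Messenger RNA of CD8+ T cells isolated from mouse liver was sequenced in bulk from 2 groups of 3 libraries each, a control group and a group carrying the label CUMS. The labels do not spell that abbreviation out, and the series text places the study in chronic stress and liver CD8+ T cell damage. CD8+ T cells are the lymphocytes that kill infected or transformed cells. The series title also names the hepatic kynurenine pathway, a route of tryptophan breakdown, and liver cancer. The deposited values were raw read counts for 54532 genes. Total counts were 17985688, 18023206 and 17642478 in control replicates 1, 2 and 3, and 18012387, 15798759 and 14902248 in CUMS replicates 1, 2 and 3. The labels do not say whether the replicates of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

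CUMS replicates 2 and 3 stood apart from the other 4 libraries. Reads fell on 15012 and 14670 genes in them, against 19713, 19479 and 17616 genes in the controls and 20292 in CUMS replicate 1. Among the 1265 genes with a mean of 1 to 2 CPM (counts scaled to a common library total), 19.8% (95% exact binomial interval 17.7 to 22.1) had no read in CUMS replicate 2 and 22.4% (20.1 to 24.8) had none in CUMS replicate 3. The share was 0.079% in control replicate 1 and in CUMS replicate 1, 0.474% in control replicate 2 and 1.98% in control replicate 3. No library lacked reads for any of the 1734 genes of 10 to 20 CPM. The first principal component of log2 CPM held 40.3% of the variance and set CUMS replicate 3 apart, and the second held 35.7% and set CUMS replicate 2 apart. CUMS replicate 1 correlated with the controls at r = 0.965 to 0.975 across genes, which are not independent replicates, and with CUMS replicates 2 and 3 at 0.938 and 0.932.

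**Figure D1:**
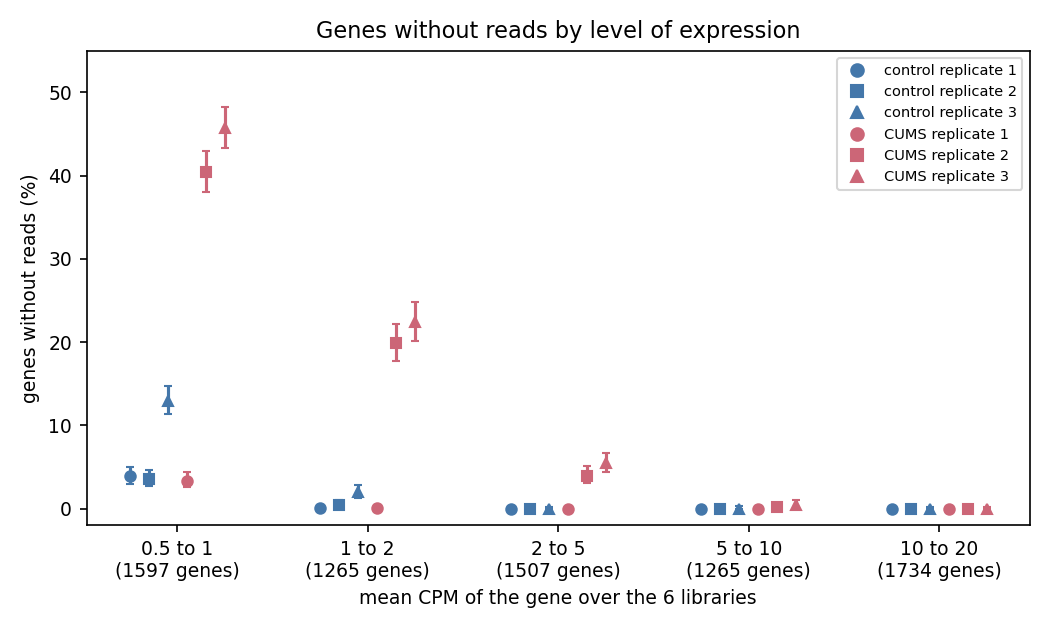
The x axis groups genes by their mean CPM over the 6 libraries, and the y axis gives the percentage of them without a read in each library, with 95% exact binomial intervals that cover counting error only. CUMS replicates 2 and 3 lie at 19.8% and 22.4% among genes of 1 to 2 CPM, and the other 4 libraries at 1.98% or less.

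The comparison of CUMS with control asked which transcripts differed between the libraries of isolated liver CD8+ T cells, which also held transcripts of other cell types. The genes lower in CUMS included the heat shock protein Hsph1, 3.76-fold lower (log2 fold change -1.91 ± 0.13 SE, n = 3 and 3), the coreceptor Cd4, 2.45-fold lower, and Cd300e, an activating receptor of monocytes, 5.74-fold lower (-2.52 ± 0.41). Genes higher in CUMS included the tetraspanin Tspan9, 3.38-fold higher (1.76 ± 0.18), the cold-inducible RNA-binding protein Cirbp, 2.36-fold higher (1.24 ± 0.18), and the coreceptor Cd8a, 1.48-fold higher. Of 14054 genes tested with edgeR's quasi-likelihood test, 184 passed a Benjamini-Hochberg adjusted p of 0.05, 51 of them higher and 133 lower in CUMS. Of these, 18 were higher and 59 lower by over 2-fold. The values of the groups did not overlap for any of the 184 genes, nor for 22.7% of all genes tested, where chance gives 10%.

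The 10 protein-coding genes with the largest rise were Gm47283, Tspan9, Tcta, Cirbp, Naglu, Zc3h6, Aasdh, Smpd5, Slc16a5 and Zkscan8, with log2 fold changes from 1.12 to 1.77. Tspan9 (ENSMUSG00000030352, mm10 chromosome 6, 127961396 to 128143594, minus strand) had 17.96 ± 1.42 CPM in control and 60.7 ± 11.9 in CUMS (SD, n = 3; edgeR adjusted p = 0.00169). Cirbp (chromosome 10, 80165985 to 80172786, plus strand) had 35.1 ± 9.03 CPM in control and 82.8 ± 3.92 in CUMS (edgeR adjusted p = 0.0132). Naglu, a lysosomal enzyme of heparan sulfate breakdown, had a log2 fold change of 1.22 ± 0.25. The 10 with the largest fall were Cd300e, Thbs1, Il1rl1, Hsph1, St3gal2, Wfdc17, Hmox1, Maf, Nfil3 and Hlx, with log2 fold changes from -2.52 to -1.47. In the same libraries the monocyte and neutrophil markers had a median log2 fold change of -0.78 and the CD4 T cell markers -1.22. Whether these falls lay in CD8+ T cells or in other cells was not told apart. Cd300e (chromosome 11, 115051917 to 115062177) had 11.7 ± 2.499 CPM in control and 2.03 ± 0.906 in CUMS (edgeR adjusted p = 0.0186). Thbs1, the secreted glycoprotein thrombospondin 1, had a log2 fold change of -2.29 ± 0.47. Il1rl1, the receptor for interleukin 33, fell by 1.98 ± 0.30 on the log2 scale, and the transcription factors Maf and Nfil3 fell by 1.51 ± 0.23 and 1.47 ± 0.30. Without a stated strand setting, the values of Tcta, Smpd5, Zc3h6, Slc16a5, Thbs1, St3gal2 and Maf are uncertain, since each overlaps a gene on the opposite strand in the deposited coordinates, Rhoa for Tcta and Oplah for Smpd5. Tspan9, Zc3h6 and St3gal2 also overlap a gene on their own strand.

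The number of genes past the threshold depended on single libraries. It was 62, 19 and 46 without control replicate 1, 2 or 3, and 92, 9 and 178 without CUMS replicate 1, 2 or 3. It was 7 without CUMS replicates 2 and 3 together, an alternative added after the data were seen. Of the genes named above, Tspan9, Hsph1 and Cd4 passed in each of the 6 fits that left out 1 library. Cirbp and Wfdc17 missed the threshold only without CUMS replicate 2 (edgeR adjusted p = 0.063 for both), and the others missed it in 3 to 5 of those fits. All 184 genes kept their sign in each of these fits, which the lack of overlap between their groups nearly fixes beforehand. DESeq2 called 665 genes and limma voom with sample weights 497. With the level of monocyte and neutrophil markers as a covariate, edgeR called 0 genes, with 193 at an unadjusted p under 0.05. With the level of hepatocyte markers it called 2. The groups did not overlap in either level. In mean log2 CPM, monocyte and neutrophil markers had 6.31 to 6.89 in control and 5.64 to 5.81 in CUMS, and hepatocyte markers 0.73 to 1.86 and 2.02 to 2.11. Such fits only partly separate marker level from group, so the loss of calls does not show where the differences came from.

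**Figure D2:**
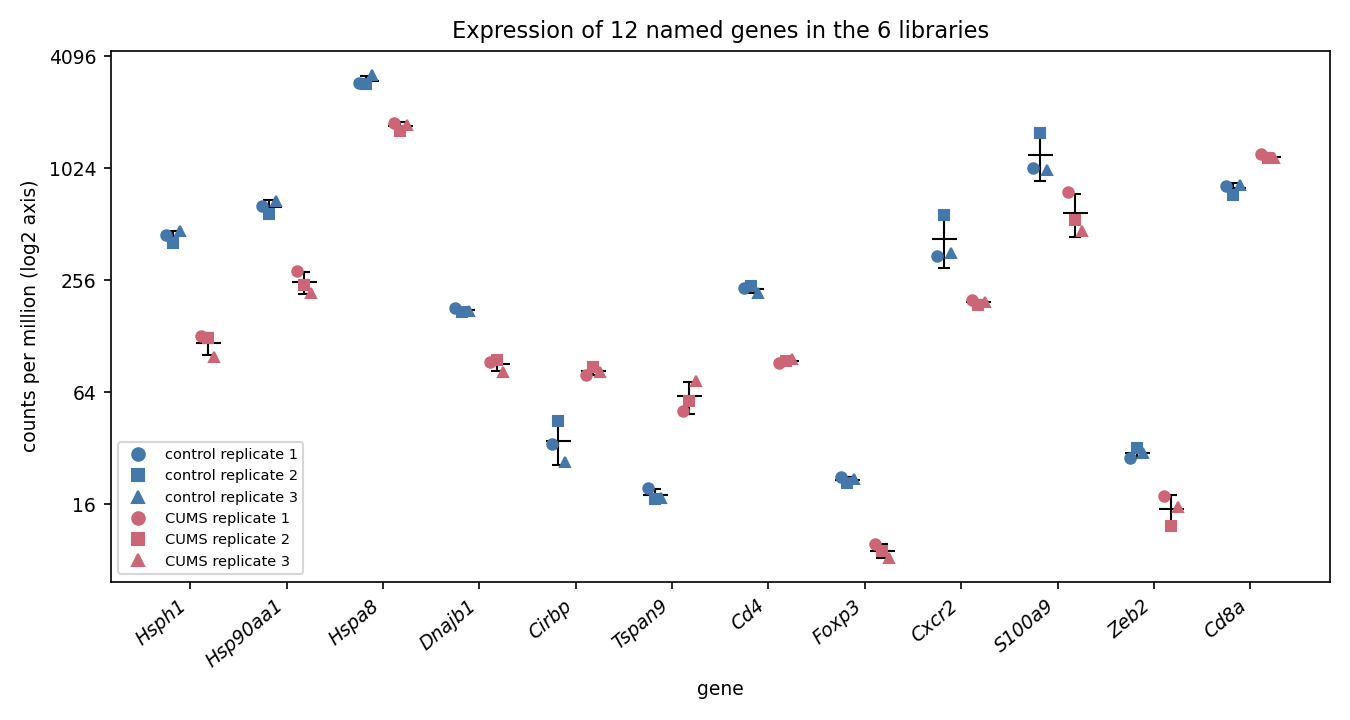
The y axis (log2 scale) gives CPM scaled by edgeR's library factors for 12 named genes on the x axis; each point is a library, and bars show the mean ± SD of 3 libraries. Hsph1 lies between 408 and 469 CPM in the controls and between 99.1 and 129 in CUMS, and Cd4 between 218 and 239 CPM in the controls and between 91.8 and 96.4 in CUMS.

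Of 13 measured genes of the heat shock response, which encode chaperones that fold and protect proteins, 9 fell in CUMS, 0 rose and 4 did not pass; adjusted over the list alone, 10 fell. Hsph1 (ENSMUSG00000029657, mm10 chromosome 5, 149614287 to 149636376, minus strand) went from 443 ± 31.6 CPM in control to 118 ± 16.2 in CUMS (SD, n = 3; edgeR adjusted p = 9.34e-05). Hsp90aa1, the inducible form of the chaperone HSP90, went from 635 ± 53.4 to 250 ± 34.2 CPM (chromosome 12, 110690605 to 110702728; edgeR adjusted p = 0.001). Hspa8, the constitutive HSP70 chaperone and the most abundant gene named here in the controls, went from 3037 ± 196 to 1721 ± 90.7 CPM (edgeR adjusted p = 0.00369). Dnajb1, an HSP40 cochaperone, went from 177 ± 4.51 to 90.2 ± 7.16 CPM (edgeR adjusted p = 0.00369). The median log2 fold change of the list was -0.92 (camera adjusted p = 9.81e-09; adjusted p = 0.0909 with an estimated correlation). The unfolded protein response list, genes of protein folding in the endoplasmic reticulum, moved in the same direction with a median of -0.28 over 19 members (camera adjusted p = 0.000854; adjusted p = 0.151 with an estimated correlation). Its only member past the threshold was the chaperone Hsp90b1, which fell by 0.57 ± 0.12 on the log2 scale; adjusted over the list alone, 4 fell. Hspa5, the chaperone BiP, had a log2 fold change of -0.43 ± 0.10 and missed the threshold (edgeR adjusted p = 0.0568). In the same libraries the monocyte and neutrophil markers had a median log2 fold change of -0.78.

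Hsph1, Hsp90aa1 and Dnajb1 passed in each of the 6 fits that left out 1 library, Hspa8 missed the threshold without CUMS replicate 2 (edgeR adjusted p = 0.051), and Hsp90b1 missed it in all 6. The median of the unfolded protein response list was -0.19 without CUMS replicate 2, and with the monocyte and neutrophil marker level as a covariate the list missed the threshold (camera adjusted p = 0.0533). Hspa8 overlaps small nucleolar RNA genes, Hsp90b1 overlaps a gene on the opposite strand, and heat shock protein genes have near-identical processed copies in the genome among which counting could split reads, so their levels are uncertain to that extent.

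Markers of other cell types were measured in the same libraries. Of 14 measured markers of CD4 T cells, NKT cells and gamma delta T cells, 4 fell. Cd4 went from 230 ± 11.2 to 94.0 ± 2.30 CPM (ENSMUSG00000023274, mm10 chromosome 6, 124864692 to 124888221, minus strand; edgeR adjusted p = 0.000362). The others were the regulatory T cell factor Foxp3 (log2 fold change -1.26 ± 0.20), the CD40 ligand gene Cd40lg (-1.19 ± 0.22) and the CD4 lineage factor Zbtb7b (-1.02 ± 0.17). Adjusted over the list alone, 7 fell. The median was -1.22 (camera adjusted p = 7.78e-08; adjusted p = 0.0909 with an estimated correlation). Of 15 monocyte and neutrophil markers, 4 fell, and 11 fell adjusted over the list alone. The chemokine receptor Cxcr2 went from 428 ± 130 to 195 ± 6.04 CPM (edgeR adjusted p = 0.0164), and the calcium-binding protein gene S100a9, abundant in neutrophils, from 1209 ± 335 to 591 ± 156 CPM (edgeR adjusted p = 0.0363). The lipopolysaccharide coreceptor Cd14 (-1.33 ± 0.27) and the chemokine receptor Ccr2 (-0.68 ± 0.14) also fell. The median was -0.78 (camera adjusted p = 7.53e-06; adjusted p = 0.194 with an estimated correlation). Of 9 Kupffer cell and macrophage markers, 3 fell, and 5 fell adjusted over the list alone: the haem oxygenase Hmox1 (-1.57 ± 0.29), the iron exporter Slc40a1 (-0.91 ± 0.18) and Cd68 (-1.07 ± 0.23) passed over all genes. That list had a median of -0.81 (camera adjusted p = 0.000354; adjusted p = 0.194 with an estimated correlation). None of 14 markers of NK cells and related innate lymphocytes passed over all genes and 3 fell adjusted over the list alone, with a median of -0.66 (camera adjusted p = 0.0016; adjusted p = 0.151 with an estimated correlation).

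The remaining marker lists did not pass camera's list test with all 6 libraries and no covariate. Dendritic cell markers had a median log2 fold change of -0.64 over 11 members (camera adjusted p = 0.108) and B cell and plasma cell markers -0.30 over 17 (0.167). No member of either passed over all genes; adjusted over the list alone, 2 B cell and plasma cell markers fell. Jchain, the joining chain of secreted antibodies, had a log2 fold change of -1.04 ± 0.23 (edgeR adjusted p = 0.0511). Among hepatocyte markers, albumin, Alb, had 5.59 ± 1.17 CPM in control and 7.59 ± 1.32 in CUMS (edgeR adjusted p = 0.586), and haptoglobin, Hp, had 192 ± 69.7 and 108 ± 10.2 CPM (0.0795). The list of 9 had a median of 0.94 (camera adjusted p = 0.178), and 1 member fell adjusted over the list alone. Hp lay far above Alb in each group, and which cells its reads came from was not tested. Liver endothelial markers (6 measured, median 0.24, camera adjusted p = 0.22), stellate cell, fibroblast and cholangiocyte markers (5, -0.89, 0.209) and erythroid and platelet markers (3, -0.76, 0.986) had no member past the threshold over all genes, and adjusted over the list alone 1 stellate cell, fibroblast and cholangiocyte marker fell. Cd4 passed in each of the 6 fits that left out 1 library, Cxcr2 missed the threshold without CUMS replicate 1 or 2 (edgeR adjusted p = 0.054 and 0.077), and the other 9 called markers missed it in 4 to 6 of them. Foxp3 and Zbtb7b overlap a gene on the opposite strand. Over the alternatives the hepatocyte median ran from -0.34 to 1.68, so its sign was not stable. It was 0.054 without CUMS replicates 2 and 3 together and 1.68 with the monocyte and neutrophil covariate, where that list passed (camera adjusted p = 0.00325), as it did with a replicate block (0.045). The NK cell list and the Kupffer cell and macrophage list missed the threshold with that covariate (0.414 and 0.516). The dendritic cell list passed with a replicate block (0.045) and without genes on more than 1 list (0.0218), and the B cell and plasma cell list passed as lower without CUMS replicate 2 (0.0451). The B cell and plasma cell median was -0.34 without CUMS replicates 2 and 3 together. The liver endothelial list passed by fry (fry adjusted p = 0.0413).

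**Figure D3:**
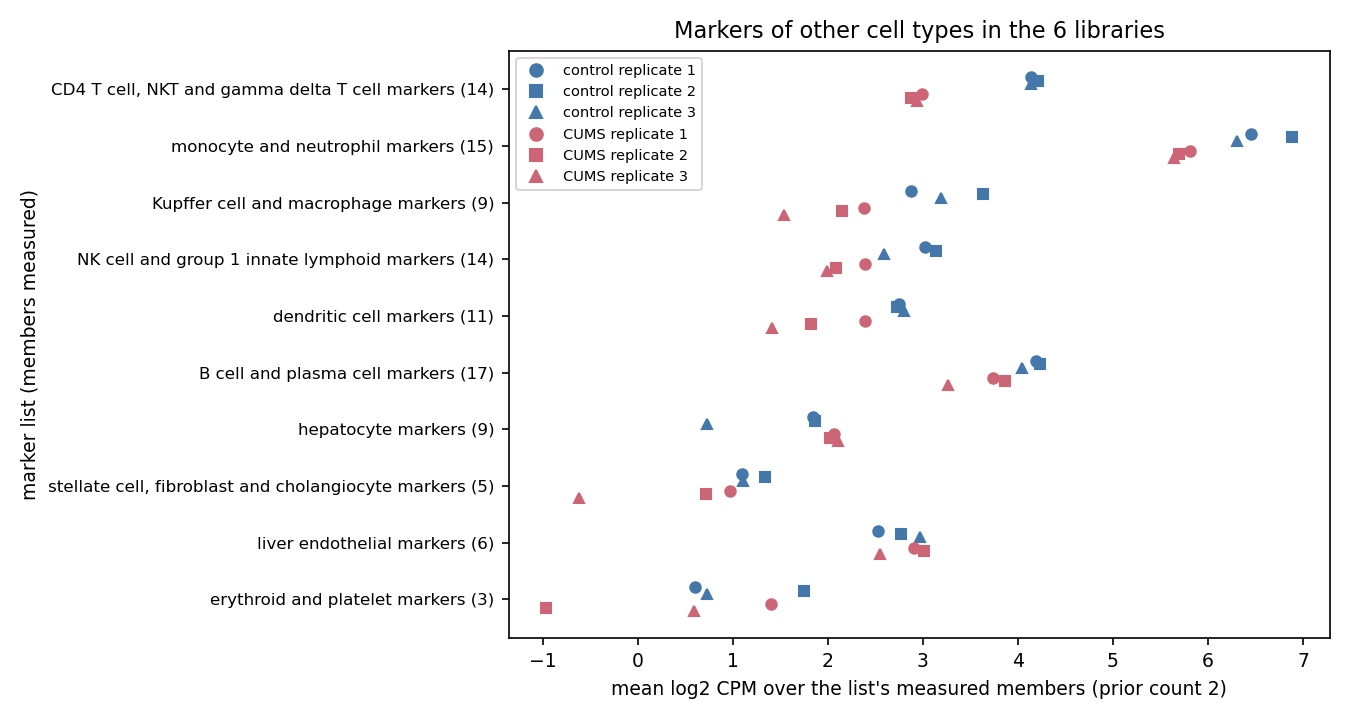
The x axis gives the mean log2 CPM (prior count 2) over the measured members of each of 10 marker lists, and each point is a library. The CD4 T cell, NKT and gamma delta T cell list lies between 4.14 and 4.21 in the controls and between 2.87 and 2.99 in CUMS, and the monocyte and neutrophil list between 6.31 and 6.89 in the controls and between 5.64 and 5.81 in CUMS.

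Of the T cell identity genes, Cd8a rose in CUMS. It (chromosome 6, 71373427 to 71379173) went from 800 ± 51.7 to 1180 ± 32.8 CPM (SD, n = 3; log2 fold change 0.56 ± 0.09, edgeR adjusted p = 0.0225). It was the only 1 of 15 members past the threshold, over all genes and adjusted over the list alone. Cd8b1 (0.27 ± 0.11), Cd3e (0.26 ± 0.11) and the T cell receptor constant gene Trbc2 (0.31 ± 0.11), which has a near-identical copy, missed it. The list's median was 0.16, with 13 members positive and 2 negative (camera adjusted p = 0.0219; adjusted p = 0.402 with an estimated correlation and 0.0773 by fry). Of 16 genes of effector differentiation, 2 fell and 14 did not pass. Zeb2, a transcription factor of terminal effector cells, fell (-0.99 ± 0.19, edgeR adjusted p = 0.0326). Il2rb, a chain of the interleukin 2 and 15 receptors, fell from 678 ± 37.0 to 480 ± 39.3 CPM (edgeR adjusted p = 0.0419). Adjusted over the list alone, 11 fell and 1 rose, and the median was -0.47 (camera adjusted p = 3.4e-05; adjusted p = 0.151 with an estimated correlation). Id2 (-0.81 ± 0.18) and Cd44 (-0.59 ± 0.13) missed the threshold over all genes (edgeR adjusted p = 0.0553 and 0.0566). Of 20 inhibitory receptors and exhaustion genes, 2 fell: the ectonucleotidase Entpd1, which encodes CD39, from 90.3 ± 23.1 to 45.05 ± 0.743 CPM (edgeR adjusted p = 0.0225), and the receptor Cd244a (-1.12 ± 0.24, edgeR adjusted p = 0.0448). Adjusted over the list alone, 5 fell, and the median was -0.63 (camera adjusted p = 6.82e-05; adjusted p = 0.111 with an estimated correlation). Pdcd1, which encodes PD-1, had 10.4 ± 1.86 CPM in control and 5.94 ± 2.32 in CUMS (edgeR adjusted p = 0.292).

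Of 20 cytotoxic effector molecules, the granule proteoglycan gene Srgn fell (-0.55 ± 0.11, edgeR adjusted p = 0.0379) and the other 19 did not pass; adjusted over the list alone, 4 fell and 1 rose. The list's median was -0.24 (camera adjusted p = 0.0177; adjusted p = 0.38 with an estimated correlation and 0.0773 by fry). It missed the threshold with genes of at least 10 CPM only, too. The protease gene Gzmb had a log2 fold change of -0.51 ± 0.15 (edgeR adjusted p = 0.125), the pore-forming protein gene Prf1 -0.28 ± 0.12 (0.292) and the chemokine Ccl5 -0.65 ± 0.16 (0.0717), while the protease gene Ctsw had 0.52 ± 0.12 (0.0587). Ifng, which encodes interferon gamma, had 97, 72 and 54 counts in control replicates 1, 2 and 3, 47 in CUMS replicate 1 and 0 in CUMS replicates 2 and 3, and missed the threshold (edgeR adjusted p = 0.456). Its mean lies between 2 and 5 CPM, where those 2 libraries lacked reads for 3.98% and 5.44% of genes. Of 18 naive and central memory genes, none passed in either adjustment, and the list as a set was higher with a median of 0.12 (camera adjusted p = 0.0123; adjusted p = 0.324 with an estimated correlation). The survival gene Bcl2 had a log2 fold change of 0.37 ± 0.10 (edgeR adjusted p = 0.0998) and the transcription factor Tcf7 0.15 ± 0.09 (0.511). Tissue residency genes did not pass as a set with camera (14 measured, median -0.13, camera adjusted p = 0.224) but did with fry (fry adjusted p = 0.0147). The regulator Rgs2 (-0.70 ± 0.15) and the AP-1 factor Fosl2 (-1.02 ± 0.18) fell, and the integrin Itgae, which encodes CD103, had 0.49 ± 0.11 (edgeR adjusted p = 0.0545). Adjusted over that list alone, 5 fell and 3 rose.

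In the same libraries the CD4 T cell markers had a median log2 fold change of -1.22 and the monocyte and neutrophil markers -0.78, and Zeb2, Cd244a, Cd3e, Cd44, Bcl2, Tcf7 and Itgae overlap a gene on the opposite strand. Cd8a missed the threshold without control replicate 1 or 2 or CUMS replicate 2 (edgeR adjusted p = 0.073, 0.15 and 0.082), Fosl2 missed it in 3 of the 6 fits that left out 1 library, and Zeb2, Il2rb, Entpd1, Cd244a, Srgn and Rgs2 in 4 to 6. With the monocyte and neutrophil marker level as a covariate the list of inhibitory receptors and exhaustion missed it (median -0.28), Entpd1 and Cd244a had -0.12 and -0.16, and the T cell identity, cytotoxic and naive and central memory lists missed it too (camera adjusted p = 0.117, 0.45 and 0.919). The T cell identity list missed it without control replicate 3 or CUMS replicate 1 or 3 (camera adjusted p = 0.098, 0.11 and 0.057). The naive and central memory list missed it without control replicate 2 (median 0.078, camera adjusted p = 0.078). The cytotoxic and the naive and central memory lists missed it without CUMS replicates 2 and 3 together.

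Genes of hormone signalling were measured because the series concerns stress. The glucocorticoid receptor gene Nr3c1 went from 268 ± 24.6 to 192 ± 7.15 CPM (SD, n = 3; log2 fold change -0.48 ± 0.11) and missed the threshold (edgeR adjusted p = 0.0557). The 5 measured stress hormone receptor genes did not pass as a set with camera (camera adjusted p = 0.688) but did with fry (fry adjusted p = 0.0485). Their median was -0.29 and their mean 0.068, which differ in sign, and 1 fell adjusted over the list alone. Of 18 glucocorticoid response genes, 2 fell: the chemokine receptor Cxcr4 (-0.70 ± 0.14, edgeR adjusted p = 0.0387) and Rgs2 (-0.70 ± 0.15, edgeR adjusted p = 0.0423). Adjusted over the list alone, 8 fell and 2 rose, and the median was -0.40 (camera adjusted p = 0.0018; adjusted p = 0.194 with an estimated correlation). The receptor's targets Tsc22d3 and Fkbp5 had log2 fold changes of -0.15 ± 0.09 and -0.34 ± 0.14 and did not pass (edgeR adjusted p = 0.527 and 0.289). In the same libraries the monocyte and neutrophil markers had a median of -0.78. The list missed the threshold without CUMS replicate 1 (camera adjusted p = 0.066) and without genes on more than 1 list (0.0636), and with the marker level as a covariate its median was -0.18 (0.422) and Rgs2 had 0.043. Without CUMS replicates 2 and 3 together the median of the glucocorticoid response list was -0.18 as well.

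Of the kynurenine pathway genes, Haao rose in CUMS. Haao, the enzyme that makes the precursor of quinolinic acid, went from 17.98 ± 2.18 to 33.8 ± 3.26 CPM (SD, n = 3; mm10 chromosome 17, 83831356 to 83846790; log2 fold change 0.91 ± 0.18, edgeR adjusted p = 0.0334). It was the only 1 of 8 measured members past the threshold, over all genes and adjusted over the list alone. Ido1, the first enzyme of the pathway outside the liver parenchyma, had 0 counts in each of the 6 libraries. Counting error alone allows up to 0.166 to 0.201 CPM at a floor of 3 counts per library. For CUMS replicates 2 and 3 that floor is too low, as 19.8% and 22.4% of genes of 1 to 2 CPM had no read in them. Intervals and floors cover counting error only. Kmo had 3.71 ± 1.51 CPM in control and 3.63 ± 1.38 in CUMS (edgeR adjusted p = 0.989). The pathway did not pass as a set (camera adjusted p = 0.424), and its median of -0.0039 and mean of 0.0075 differ in sign. Among 10 genes of kynurenine and amino acid transport, the cystine transporter Slc7a11 fell (-1.42 ± 0.30, edgeR adjusted p = 0.0438), while Slc7a5, which carries large neutral amino acids, had 0.73 ± 0.17 (0.0587) and the glutamine carrier Slc1a5 0.41 ± 0.11 (0.0822). Adjusted over that list alone, 2 rose and 2 fell; the set did not pass (camera adjusted p = 0.351), and its median of 0.062 and mean of -0.003 differ in sign. The aryl hydrocarbon receptor Ahr, which binds kynurenine, had 10.1 ± 2.57 CPM in control and 7.63 ± 1.69 in CUMS (edgeR adjusted p = 0.59). Of the 6 measured genes of its pathway, the chaperone Hsp90ab1 fell (-0.52 ± 0.09, edgeR adjusted p = 0.0216), in both adjustments, and the set did not pass (median -0.17, camera adjusted p = 0.268). Kmo, Ahr, Slc7a5 and Slc7a11 overlap a gene on the opposite strand. Haao missed the threshold in each of the 6 fits that left out 1 library, as did Cxcr4, with log2 fold changes of 0.80 to 0.97 and -0.86 to -0.59. Slc7a11 missed it in 5 of them, and Hsp90ab1 without control replicate 1 or 2 or CUMS replicate 2 (edgeR adjusted p = 0.076, 0.097 and 0.086).

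Among genes of signalling and adhesion, the activation-induced AP-1 genes Fos (316 ± 74.8 to 184 ± 2.54 CPM, SD, n = 3) and Jun (116 ± 8.92 to 80.2 ± 1.33 CPM) fell and the growth regulator Myc rose (87.4 ± 7.63 to 137 ± 21.6 CPM; edgeR adjusted p = 0.0316, 0.046 and 0.0448). The 20 immediate early genes did not pass as a set (median -0.43, camera adjusted p = 0.175), except without control replicate 3 (-0.52, 0.0257); adjusted over the list alone, 8 fell and 5 rose. Of 20 chemokine receptors and adhesion molecules, 3 fell: the integrin chain Itgb1, from 395 ± 11.9 to 240 ± 23.4 CPM (edgeR adjusted p = 0.0136), Ccr2 and Cxcr4. Adjusted over the list alone, 4 fell, and the median was -0.20 (camera adjusted p = 0.00709; adjusted p = 0.194 with an estimated correlation). Of 18 cytokines and cytokine receptors of T cells, Il2rb and the interferon gamma receptor gene Ifngr1 (-0.50 ± 0.11, edgeR adjusted p = 0.0466) fell. With p adjusted over the list alone, 7 fell and 1 rose, and the median was -0.11 (camera adjusted p = 0.0177; adjusted p = 0.261 with an estimated correlation). Of 19 NF-kB and TNF signalling genes, the transcriptional cofactor Bcl3 fell (-0.82 ± 0.16, edgeR adjusted p = 0.0315) and 4 fell adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0499; adjusted p = 0.324 with an estimated correlation). Of 24 T cell receptor signalling and costimulation genes, the costimulatory receptor Icos fell (-0.70 ± 0.12, edgeR adjusted p = 0.0225), in both adjustments, and the set did not pass (median -0.0028, camera adjusted p = 0.688). The monocyte and neutrophil markers, median -0.78, include Ccr2.

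Among genes of cell division and survival, the proliferation marker Mki67 fell from 117 ± 18.2 to 68.1 ± 3.66 CPM (SD, n = 3; edgeR adjusted p = 0.0225) and was the only 1 of 28 cell cycle and DNA replication genes past the threshold. In all 2 fell adjusted over the list alone, and the median was -0.27 (camera adjusted p = 0.00257; adjusted p = 0.151 with an estimated correlation). The anti-apoptotic gene Mcl1 fell from 1095 ± 85.8 to 704 ± 51.1 CPM (edgeR adjusted p = 0.0188). Of 25 apoptosis genes no other passed, and 2 fell and 1 rose adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.041; adjusted p = 0.324 with an estimated correlation). None of 16 p53 targets passed over all genes and 6 fell adjusted over the list alone, with a median of -0.41 (camera adjusted p = 0.00424; adjusted p = 0.194 with an estimated correlation). Of 20 oxidative stress response genes, Hmox1 and Slc7a11 fell, and 5 fell adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.0182; adjusted p = 0.324 with an estimated correlation). Hmox1 is also on the Kupffer cell and macrophage list, whose median was -0.81.

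Without CUMS replicate 1 the lists of chemokine receptors and adhesion, cytokine receptors and oxidative stress missed the threshold (camera adjusted p = 0.066, 0.069 and 0.066). So did the NF-kB list (0.36), which also missed it without control replicate 1 or 2 (0.058 and 0.18), with median-of-ratios factors, no filter, the replicate block or genes on 1 list only, and by fry, in 10 of its 17 alternatives. The cytokine and oxidative stress lists also missed it with genes on 1 list only, and the apoptosis list without a filter, with genes of at least 10 CPM only and by fry. The apoptosis list missed it without control replicate 2 or 3 or CUMS replicate 1 or 3 (0.056, 0.076, 0.098 and 0.054). The median of the NF-kB list was -0.049 without control replicate 2, -0.19 without control replicate 3 and -0.20 without CUMS replicate 2. That of the cytokine list was -0.28 and -0.19 without CUMS replicate 2 or 3, and that of the oxidative stress list -0.20 without control replicate 2. With the monocyte and neutrophil marker level, whose markers had a median of -0.78, as a covariate, the p53 list had a median of -0.095 (camera adjusted p = 0.776). The chemokine, cytokine, NF-kB, oxidative stress and apoptosis lists missed the threshold too (0.0972, 0.066, 0.919, 0.919 and 0.428). Itgb1 and Mcl1 missed it only without control replicate 2 (edgeR adjusted p = 0.066 and 0.12) or CUMS replicate 2 (0.069 for both). Fos, Jun, Myc, Ifngr1, Bcl3, Icos, Mki67, Hmox1 and Slc7a11 missed it in 4 to 6 of the 6 fits that left out 1 library. The oxidative stress and apoptosis lists also missed it without CUMS replicates 2 and 3 together, and Jun, Bcl3 and Mki67 overlap a gene on the opposite strand.

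Metabolic, antigen presentation and interferon genes did not pass as sets with all 6 libraries and no covariate. The 31 measured type I interferon response genes had a median log2 fold change of -0.084 (camera adjusted p = 0.394) and none passed in either adjustment. The 19 genes of MHC and antigen presentation had a median of 0.14 (camera adjusted p = 0.0794) with 1 higher and 1 lower adjusted over the list alone; Nlrc5, an activator of MHC class I genes, had 0.41 ± 0.11 (edgeR adjusted p = 0.085). The 68 nuclear oxidative phosphorylation genes had a median of 0.062 (camera adjusted p = 0.175), the 80 cytosolic ribosomal protein genes 0.031 (0.22), the 12 mitochondrially encoded genes -0.075 (0.351) and the 18 fatty acid oxidation genes 0.019 (0.744), with none past the threshold in either adjustment. Of 22 glycolysis genes, Myc rose and the set did not pass (median -0.18, camera adjusted p = 0.214); adjusted over the list alone, 1 rose and 2 fell, and the lactate exporter Slc16a3 had -1.28 ± 0.35 (edgeR adjusted p = 0.0973). Of 15 genes of NAD metabolism none passed over all genes and 1 rose adjusted over the list alone (median -0.32, camera adjusted p = 0.394); Nmnat2, an enzyme of NAD synthesis, had 1.10 ± 0.25 (edgeR adjusted p = 0.0587). The oxidative phosphorylation list passed as higher without control replicate 1 (median 0.089, camera adjusted p = 0.0368) and without CUMS replicate 2 (0.14, 0.0152). The ribosomal protein list passed as higher without control replicate 1, CUMS replicate 2 or CUMS replicate 3 (medians 0.082, 0.12 and 0.11, camera adjusted p = 0.0434, 0.0139 and 0.0224). The MHC list did so without control replicate 1 (0.21, 0.0368). With the monocyte and neutrophil marker level as a covariate these lists also passed as higher (medians 0.28, 0.40 and 0.28). Without CUMS replicates 2 and 3 together, which leaves 1 CUMS library, the oxidative phosphorylation and ribosomal protein medians were 0.29 and 0.36. The calls of these lists rest on the preset correlation of 0.01. Estimated correlations were 0.37 for oxidative phosphorylation, 0.68 for ribosomal protein and 0.27 for MHC genes. With them and all 6 libraries no list of these passed (camera adjusted p = 0.791, 0.855 and 0.559). In all, 19 of 40 lists passed with camera's preset correlation, 17 lower and 2 higher in CUMS, and 0 passed with an estimated correlation, where 10 had an unadjusted p under 0.05; fry, which tests whether a list's genes move one way on balance, passed 18. Camera passed 12 without CUMS replicate 1 and 8 with the level of monocyte and neutrophil markers as a covariate, which was added after the data were seen.

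**Figure D4:**
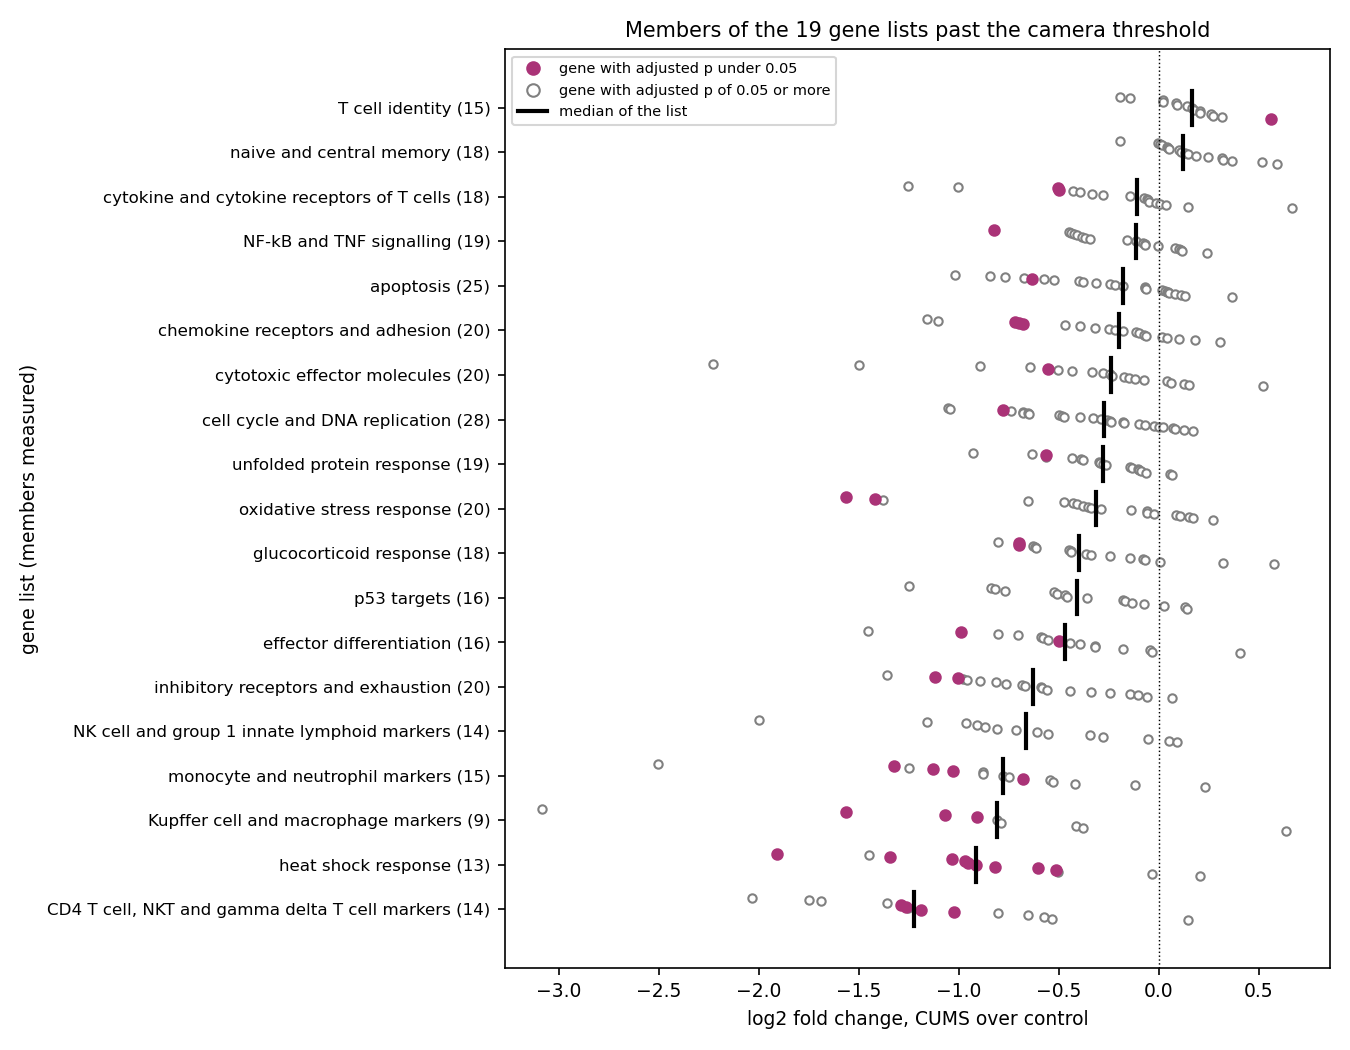
The x axis gives the log2 fold change of CUMS over control for each measured member of the 19 lists on the y axis that passed with camera's preset correlation; filled points are genes past an edgeR adjusted p of 0.05 and vertical bars are list medians. The medians run from -1.22 for the CD4 T cell, NKT and gamma delta T cell markers and -0.92 for the heat shock response to 0.16 for T cell identity.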

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

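The fits without CUMS replicates 2 and 3, with genes of at least 10 CPM only, with the monocyte and neutrophil marker level as a covariate and with the GC trend removed were chosen after the data were seen. All 184 called genes kept their sign wherever they were tested, except with the monocyte and neutrophil covariate, where 171 did. In fits without a covariate, the lack of overlap between the groups nearly fixes the sign of these genes beforehand. The count of changed genes was 186 with median-of-ratios factors, 172 with library size alone and 170 without marker genes. It was 704 (205 higher, 499 lower) without a filter, 316 (108 and 208) with the stricter filter, 280 (83 and 197) for protein-coding genes only and 368 (129 and 239) for genes of at least 10 CPM. It was 665 (232 and 433) with DESeq2, 497 (205 and 292) with voom and 301 (99 and 202) with the GC trend removed. Requiring a log2 fold change over 1 left 77 (18 and 59), by construction. The replicate number as a block gave 71 (10 and 61). It was fixed beforehand not to treat the numbers as pairs, because the labels do not say that a number marks a shared batch or litter. Deviations of same-numbered libraries correlated at r = 0.0137, -0.0358 and -0.0369 across genes. With the hepatocyte covariate and with the monocyte and neutrophil covariate, 1521 and 193 genes had an unadjusted p under 0.05. The groups did not overlap in either covariate, so these fits only partly separate marker level from group. The count of changed genes was 2 (0 and 2) with the first and 0 (0 and 0) with the second. Without CUMS replicates 2 and 3 it was 7 (1 and 6), with fewer samples, and the lone CUMS library was assumed to vary like the controls. Leaving out each library in turn gave 9 to 178 genes, 1 to 46 higher and 8 to 132 lower, and 12 to 22 lists. For the other settings the cause was not tested.

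The count of 19 lists became 0 with an estimated correlation. For the CD4 T cell list that correlation was -0.057, below the preset 0.01, yet camera's unadjusted p rose from 3.89e-09 to 0.00331. A correlation above the preset one therefore does not account for the loss of every list. The count of lists was 8 with the monocyte and neutrophil covariate, and 16 to 20 in the other settings that kept all 6 libraries. With that covariate, log2 fold changes turned to 0.043 for Rgs2, 0.052 for Fos and 0.19 for S100a9, none past the threshold. List medians turned to -0.0053 for naive and central memory, 0.053 for oxidative stress and 0.0996 for NF-kB and TNF signalling, none past the threshold. The median of the monocyte and neutrophil markers themselves became 0.17 and missed it too. The covariate is the mean level of those markers, S100a9 among them, so their group difference shrinks by construction. For the other genes and lists the cause was not tested. Of 2415 values of 123 named genes under other settings, 1805 kept their side of the threshold, 20 of them with a change of sign where neither value passed, 411 no longer passed, 196 newly passed and 3 reversed. Of 675 list values, 587 kept their side, 50 of them with a change of sign where neither passed, 63 no longer passed, 21 newly passed and 4 reversed. Missing reads in CUMS replicates 2 and 3 limit what was seen of genes under 5 CPM. They also reach some genes of 5 to 10 CPM, of which 0.237% and 0.474% had no read. Depth gives a floor of 0.166 to 0.201 CPM for counting error, which is too low for those libraries.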

Other observations

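Several genes that miss the threshold over all genes stand beside the lists described above. Ctla4, an inhibitory receptor of activated and regulatory T cells, had a log2 fold change of -1.36 ± 0.38 SE (n = 3 and 3; edgeR adjusted p = 0.106), and Il2ra, the high-affinity chain of the interleukin 2 receptor, had -1.25 (0.0589). The adaptor genes Tyrobp and Fcer1g, shared by NK and myeloid cells, had -0.87 and -0.72 (edgeR adjusted p = 0.0627 and 0.0851). The p53 targets Ccng1 and Gadd45a had -0.51 and -0.82 (edgeR adjusted p = 0.0652 and 0.0822).

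Tests chosen only after the results were seen include those on unread genes for the heat shock and marker lists, on Rbm3, on the B cell list and on the heat shock list mean, and the fits with the monocyte and neutrophil covariate and with genes of at least 10 CPM.

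Of 13 heat shock genes 9 fell in CUMS, and unread genes in CUMS replicates 2 and 3 are argued against as the source: all 13 members had reads in both, the median was -0.92 among members of at least 10 CPM, and CUMS replicate 1 alone had a median log2 difference of -0.92 from the controls. Fewer monocytes and neutrophils are argued against as the whole source: with their marker level as a covariate the median went from -0.92 to -0.96 with the list past the threshold (camera adjusted p = 8.65e-08 with the preset correlation; without the covariate, adjusted p = 0.0909 with an estimated one), while the Kupffer cell and macrophage median went from -0.81 to -0.025. The bound set beforehand was not met, since it also asked for a member past the threshold, and 0 of 13 passed as their median SE grew from 0.126 to 0.322. The list mean, a measure chosen after that result was seen, differed by -0.91 under the covariate with a 95% interval of -1.42 to -0.40 (3 residual degrees of freedom), which leaves a partial contribution open. A handling difference such as temperature may also contribute and stays open, as Cirbp rose while Rbm3, another cold-induced gene, chosen after its values were seen, had 0.0026 ± 0.15, and an effect of the treatment stays open too. A lower share of CD4 T cells, whose marker list had a median of -1.22, was not tested as a source of the heat shock fall and stays open as well.

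Of the monocyte and neutrophil and the CD4 T cell markers, 4 of 15 and 4 of 14 fell in CUMS, and both lists missed the threshold with an estimated correlation (adjusted p = 0.194 and 0.0909). A higher share of CD8 T cells that lowers every other type alike stays open, as the test of it cannot decide. In that test the B cell list had a median of -0.14 and the CD4 list -1.25 (permutation p = 0.00318, two-sided, over 16 and 13 members). The B cell list was chosen after the results were seen, and the permutation moved genes, which are not independent, and not libraries. With the shared gene kept, the B cell median was -0.30, and without CUMS replicates 2 and 3 together it was -0.34. The NK cell, dendritic cell and Kupffer cell lists (-0.66, -0.64 and -0.81) and Jchain (-1.04) and Igkc (-0.79) were also negative. Unread genes are argued against by CUMS replicate 1 alone, with a median log2 difference of -0.93 over both lists, and controls between -0.16 and 0.31 of each other. For the CD4 list alone it was -1.14, with controls between -0.13 and 0.054. For the monocyte and neutrophil list it was -0.68, but control replicates 2 and 3 lay at 0.59 and -0.35, so that library says less there. Medians of -0.75 (monocyte and neutrophil) and -1.17 (CD4) among members of at least 10 CPM also argue against unread genes. A different purity of the isolated cells for these types and a change in the liver under the treatment stay open, since the isolation was not measured apart from the RNA.

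CUMS replicates 2 and 3 lacked reads for many low-abundance genes. Lower sequencing depth is argued against: after thinning all libraries to the smallest total, 19.9% and 22.4% of genes of 1 to 2 CPM lacked reads in them and 2.06% or less in the other 4. The same genes switched off in both is argued against as the main source by 614 genes without reads in both, 1.22 times the 505 expected from independent loss. The excess over 505 leaves a shared loss of some genes open. Few RNA molecules at the start of library preparation may be the source: the reads per molecule implied by the unread share differed by at most 1.32 times between ranges of expression. No biological explanation was tested for it beyond the shared genes.

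Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes: 184 in all, 51 higher and 133 lower, where the highest of the other splits gave 0, and 19 lists, where the highest gave 6. With 10 splits the share cannot fall under 0.1.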
